A study of Mus musculus with 8 samples.

How the data were processed

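RNA was measured in 8 samples of cultured heart muscle cells from newborn mice on spotted arrays of long oligonucleotides. Of these samples, 4 were uninfected controls and 4 were infected with Trypanosoma cruzi. Per the labels, 20 µg of total RNA per sample was labelled with a fluorescent dye that absorbs near 647 nm (samples 1 and 3 of each group) or 555 nm (samples 2 and 4), and each sample is 1 dye channel. For sample 1 of both groups the labelling protocol names the 555 nm dye and the label field the 647 nm dye. The label field was used, and the other reading was run as an alternative. The scanner, the background correction and the software are not given in the sources used here.

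The deposited table held 33600 spots, with 1 log2 value or no value for each spot and sample. Of these spots, 15569 had no value in any sample. Neither the log base nor the centring is stated per the labels, so both were read from the values. Each of the 48 blocks of 700 consecutive spots had a median of 0 in every sample (largest absolute block median 9.21e-04). With base 2, a single multiplier per block turned 100% of the values of every block into whole numbers within a tolerance of 0.05, and with base e at most 26.8% of the values of any block did so. The deposited log2 values were therefore taken as the log2 of a whole-number spot intensity over the median intensity of the reported spots of the same block, with a highest recovered intensity of 59616. A block median over reported spots depends on how many dim spots were reported, and this differed between samples. The samples had values for 13182, 9235, 16687 and 11246 spots (controls 1 to 4) and 11776, 9600, 9994 and 8768 spots (infected 1 to 4). The median of each column was 0. Over the 6191 spots with a value in all 8 samples the medians were 1.46, 0.62, 2.16 and 1.10 in the control samples. They were 1.20, 0.72, 0.76 and 0.37 in the infected samples. These medians differed by more than 0.5, the limit set before the data were examined, so the values were quantile normalized over the probes tested, and the deposited values without further scaling became an alternative. Spots without a value included bright ones, so a missing value was not read as low expression. No measure of signal over background was used here, and the number of arrays limits the precision.

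Probes were tested where at least 3 samples of each group had a value, which left 7786 probes. The test was limma's moderated test (lmFit and eBayes, without trend or robust options) with the dye as covariate, and adjusted p-values are Benjamini-Hochberg values over all probes tested, with a threshold of 0.05. Fold changes are infected minus control on the log2 scale. Errors of group means are SD, and errors of fold changes are the standard error (SE) of the limma fit. Of the 33600 spots, 18179 carried 1 gene symbol in the platform annotation, 87 carried several and 15334 were unnamed. Symbols were updated through the Entrez gene number in a RefSeq gene table for GRCm38.p6, which held 18164 of the single-symbol spots, and the platform symbol was kept for the other 15. Of the probes tested, 5392 had 1 symbol, 24 had several and 2370 had none. A gene was represented by its tested probe with the highest mean value, which gave 4710 genes. The sources used here name no genome build, so no coordinates are given.

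The lists were 24 pathway lists and 8 lists of cell type markers, fixed before the data were examined, of which 27 had at least 5 measured genes. They were tested with camera at a preset correlation of 0.01 between genes. Because some values were missing, camera was run in its rank form (cameraPR) on the moderated statistics converted to z scores. Camera with an estimated correlation and fry were run on genes with values in all 8 samples. fry tests whether the genes of a list move, on balance, in 1 direction, and does not compare the list with other genes. The score of a list in a sample is the mean of its genes that had a value in all 8 samples, and scores were compared between groups with a two-sided exact permutation test over the 70 assignments of 4 of 8 samples, whose smallest p is 0.0286.

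The named genes were also chosen by a rule set before the data were examined. They were the 12 highest and the 12 lowest fold changes among genes past the threshold with no overlap between the groups, passing over clone and predicted-gene symbols. For each list past its test they were the 4 members with the smallest p in the direction of the list and up to 2 members past the threshold in the other direction, and for other lists up to 2 members past the threshold. In addition, some genes were to be given whatever their result, among them Gja1, Nppa, Myh6, Atp2a2, Edn1, Tgfb1, Ccl2, Cxcl10, Il6, Ptgs2, Col1a1, Hmox1, Actb and Gapdh.

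Samples 1 and 2 of a group, and likewise samples 3 and 4, were labelled with opposite dyes, and their values correlated at 0.896 to 0.976 across the shared spots, against 0.606 to 0.875 for all other pairs of samples. Spots are not independent replicates. The labels do not state which samples were hybridised to the same slide. These pairs were presumed to share an array. For samples 1 and 2 this relies on the label field, since the labelling protocol names the 555 nm dye for both. Each pair was entered as a random block (duplicateCorrelation, consensus correlation 0.80) in an alternative whose values stand beside the results. The labels do not say whether the 4 samples of a group came from separate cell preparations, so p-values measure the spread between these samples, which may be technical.

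The tests were checked on simulated data with the means, spread and missing values of the 7786 probes in the comparison of infected and control samples, with 200 changed probes in each of 5 runs. With independent samples, the test without a block recovered 3.28% of the probes changed by 1 log2 unit, 48.4% of those changed by 2 and 76.4% of those changed by 3, and made 32 false calls in all runs together. With samples correlated within pairs at the consensus correlation of the data, and each pair drawn independently, the same test made 883 false calls. The test with the random block made 13 and recovered 0.299%, 13.1% and 52.7%. In the data the pairs were not independent. Residuals of control samples 1 and 2 correlated at 0.087 to 0.353 with infected samples 3 and 4. With infected samples 1 and 2 they correlated at -0.414 to -0.166. The 883 false calls therefore need not hold for the real samples. Camera called 25 of 25 simulated lists of 20 probes shifted by 1 log2 unit and 0 of 110 unshifted lists, in simulations without correlation between genes.

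The alternatives were other dye settings, the replicate number as a block, the random block, cyclic loess, median centring, filters on dim and incomplete probes, trend and robust options, other thresholds, other list tests and each sample left out. Deposited values without further scaling, 2 other treatments of the block medians, means of the presumed pairs, each presumed pair left out, a term for a structure of the samples and the count of genes without overlap in other splits were added after the data were seen. The analysis used R 4.3.3, limma 3.58.1 and statmod 1.5.0.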

Results

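Transcript levels were measured in primary cultures of heart muscle cells from newborn mice, with and without Trypanosoma cruzi, the protozoan parasite that causes Chagas disease. The cultures had been enriched for myocytes by preplating, which removes quickly attaching non-muscle cells, and treated with cytosine arabinoside to limit fibroblast growth. Infected cultures received 5 parasites per cell and were harvested at 48 hours, when about 75% of the cells held parasites per the labels. Each group had 4 samples. Between 9235 and 16687 of the 33600 spots had a value in the control samples, and between 8768 and 11776 in the infected samples. In each group, samples 1 and 2 resembled each other more than they resembled any other sample, as did samples 3 and 4. By the label field each pair carried opposite dyes, so each group was presumed to rest on 2 arrays. The comparison of the groups asks which transcripts the infection altered.

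Infected cultures had higher levels of interferon-stimulated and antigen-presentation genes. Matrix, macrophage and sarcomere genes were lower, but these 3 lists did not pass camera with an estimated correlation (adjusted p = 0.249, 0.166 and 0.110). Of 7786 probes, 68 passed the threshold, 40 of them higher and 28 lower in infected cultures, and each changed at least 2.98-fold. Of 4710 genes, 30 were higher and 17 lower. The 4 infected samples did not overlap the 4 controls for 617 genes, which is 13.1% of the genes, against 2.86% by chance if the 8 samples were independent. The other 2 splits that keep the presumed arrays whole left 435 and 776 genes without overlap, so this count does not exceed what a grouping of arrays can give. When the presumed pairs were entered as a random block, 2 probes passed the threshold (Ccl5 and Saa3), and 315 had an unadjusted p under 0.05, against 1230 without the block. The count was 6, 14, 13 and 6 without control sample 1, 2, 3 and 4 in turn, 78, 16, 40 and 13 without infected sample 1, 2, 3 and 4, and 13 probes higher and 49 lower on the deposited scale, on which the median of all probes shifted by -0.57.

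Ccl5, a chemokine that attracts T cells and monocytes, rose from -1.0 ± 0.39 (SD, n = 3) to 5.59 ± 0.50 (n = 4) on the log2 scale, a difference of 6.69 ± 0.37 (SE, limma adjusted p = 3.22e-04). Saa3, an acute-phase protein, rose by 5.23 ± 0.34 (adjusted p = 3.22e-04). With the presumed pairs as a random block their adjusted p were 2.90e-04 and 0.00734, and on the means of the pairs 0.0286 and 0.0844 (limma), so Saa3 did not pass there. Next came Zbp1, a sensor of nucleic acids, with 4.03 ± 0.63, and Rsad2, an antiviral protein induced by interferon, with 3.87 ± 0.35. The rise of Zbp1 over the controls was 2.87 in infected samples 1 and 2 and 5.19 in infected samples 3 and 4, and 1 of its 3 probes could be tested. The class I histocompatibility genes H2-T3 (3.47 ± 0.34), H2-Q10 (3.11 ± 0.46), H2-T9 (2.90 ± 0.30) and H2-K1 (2.67 ± 0.32) were also among the 12 largest rises. These genes are close copies of each other, and the probes were not checked for cross-hybridization, so which members rose is uncertain. For H2-T3 1 of 5 probes could be tested, and for H2-Q10 1 of 6. The others were Ncoa1, a nuclear receptor coactivator of which 1 of 3 probes could be tested (3.27 ± 0.38), Psmb8, a subunit of the immunoproteasome (3.27 ± 0.40), Oasl2 (2.88 ± 0.46) and Usp18, which removes the ubiquitin-like protein ISG15 from its targets (2.75 ± 0.46). The adjusted p of these 10 genes lay between 0.00371 (Rsad2) and 0.0347 (Usp18), and with the random block between 0.0737 (H2-T3) and 0.271 (Oasl2).

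Among named genes past the threshold without overlap at their brightest probe, the largest falls were those of Ecrg4 (-3.39 ± 0.48, SE) and Ttn, which encodes the giant sarcomere protein titin (-3.39 ± 0.49). For Ttn, 1 of 7 probes could be tested. Several others encode matrix proteins or enzymes that act on the matrix. They were Adamts5, an aggrecan-cleaving protease (-3.05 ± 0.35), Ccn5 (-2.95 ± 0.50), Fndc1 (-2.62 ± 0.38), Mfap4 (-2.58 ± 0.44) and Col6a1, a chain of type VI collagen (-2.56 ± 0.41). For Fndc1, 1 of 2 probes could be tested. The chemokine Cxcl12 changed by -2.74 ± 0.40, the lipolysis inhibitor G0s2 by -2.73 ± 0.36, the complement gene C1qa by -2.43 ± 0.39, Crip1 by -2.25 ± 0.38 and the slow skeletal troponin gene Tnnt1 by -2.22 ± 0.40. Their limma adjusted p lay between 0.00996 (Adamts5) and 0.0412 (Ccn5 and Tnnt1), and with the random block between 0.184 and 0.759, so none of these 12 falls passed with the block. With the block and a term for the split that joins control samples 1 and 2 with infected samples 3 and 4, 11 of them passed, and 26 of all 31 named genes past the threshold did. That term was chosen after the split was seen to hold much of the variation, so these calls are not independent of the choice.

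**Figure D1:**
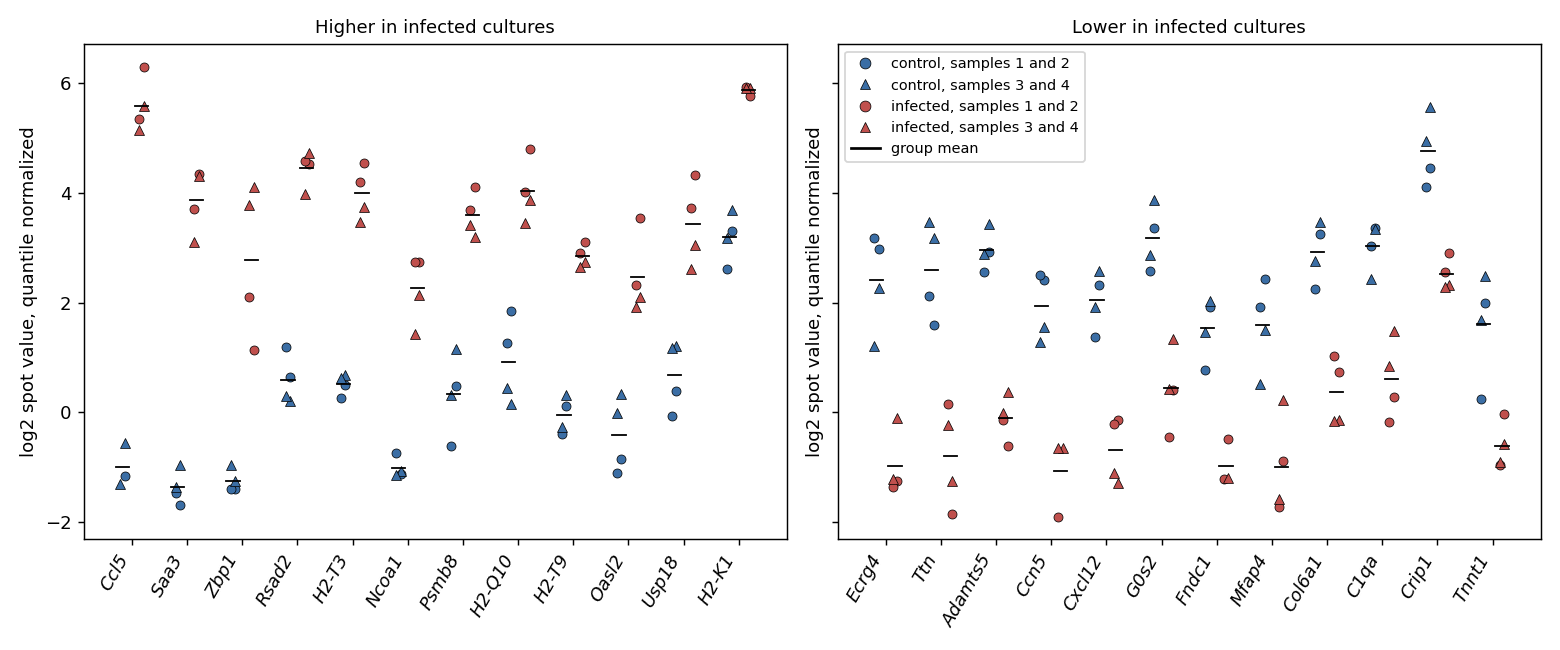
Quantile normalized log2 spot values (y axis) of the 12 genes with the largest rises and the 12 with the largest falls (x axis) among genes past the threshold, with 1 point per sample, coloured by group and shaped by presumed array. Bars are group means. The genes were chosen to have all infected values on 1 side of all control values.

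Of the 27 lists tested, 14 passed the camera test, 5 higher and 9 lower in infected cultures. Only the interferon-stimulated genes and the antigen processing list passed with an estimated correlation. The estimate for the proteasome list was 0.011, near the preset 0.01. On the same 26 genes its camera adjusted p was 7.06e-04 with the preset and 0.110 with the estimate. For the fibroblast list the estimate was -0.028, and these values were 0.00541 and 0.110. A miss with an estimated correlation therefore does not by itself show correlation between the genes of a list. With the presumed pairs as a random block 13 of the 14 passed, the exception being the ribosomal proteins. Camera ranks a list against the other genes, so these passes do not test the dependence within pairs. With the block the interferon list had a smaller adjusted p (camera, 8.67e-25), although the probes past the threshold fell from 68 to 2. With fry, 10 of the 14 passed. Fatty acid oxidation, chemokines, ribosomal proteins and calcium handling did not (fry adjusted p = 0.0643, 0.145, 0.0643 and 0.190). Both fry and the estimated correlation used only genes with values in all 8 samples. These were 7 of the 9 chemokines, without Ccl5, 5 of the 9 macrophage markers, without Lyz2, and 16 of the 21 sarcomere genes. On these 7 chemokine genes camera with the preset correlation did not pass either (adjusted p = 0.123). Counts of list members past the threshold, over all probes or over a list alone, come from the fit without the block. With the block, Ccl5 and Saa3 alone passed over all probes. Most lists differed in size between the presumed infected arrays. The medians for infected samples 1 and 2 and for infected samples 3 and 4 were -0.65 and -1.15 for the matrix, 0.45 and 0.81 for NF-kappaB, 0.27 and 0.87 for chemokines, -0.27 and -1.08 for calcium handling, -0.48 and -1.0 for the cell cycle and -0.38 and -0.16 for ribosomal proteins.

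Interferon-stimulated genes rose together. Of 23 measured, 22 had a positive fold change, and the median log2 fold change was 2.06 (camera adjusted p = 1.10e-19, and adjusted p = 0.00997 with an estimated correlation). Past the threshold over all probes were 8, all higher, and 19 when adjusted over the list alone. Besides Rsad2, Oasl2 and Usp18 these included Isg20, an RNA exonuclease, with 2.22 ± 0.31 (SE), and Ifih1, the cytosolic RNA sensor MDA5, with 2.11 ± 0.33. With the random block the limma adjusted p of Isg20 and Ifih1 were 0.434 and 0.612. For Isg20, 1 of 3 probes could be tested. The mean score of the list was 0.62 ± 0.086 (SD, n = 4) in control samples and 2.58 ± 0.18 (n = 4) in infected samples. The exact permutation p was 0.0286, the smallest possible, and 0.0643 after adjustment over the 27 lists. This test counts the 8 samples as independent, and only 3 splits keep the presumed arrays whole. The median rise was 1.86 in infected samples 1 and 2 and 1.72 in infected samples 3 and 4.

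Antigen processing and class I genes rose as well. Of 11 measured, 10 had a positive fold change, with a median of 1.63 (camera adjusted p = 6.92e-09, and adjusted p = 0.0477 with an estimated correlation). Psmb8, H2-K1, H2-D1 (2.38 ± 0.33, SE) and H2-T23 (2.49 ± 0.35) passed the threshold, and 9 of the 11 did when adjusted over the list alone. With the random block the limma adjusted p of the genes named here were 0.184, 0.247, 0.351 and 0.391. The other tested probes gave smaller values for H2-K1 (1.74 and 1.90), H2-D1 (1.14 and 2.27) and H2-T23 (0.50). The constitutive proteasome list also rose, with a median of 0.46 over 26 genes of which 23 had a positive fold change (adjusted p = 0.00101). It did not pass with an estimated correlation (adjusted p = 0.110). None of its genes passed the threshold over all probes and 1 did when adjusted over the list alone. The smallest p belonged to Psmd3 (2.07 ± 0.43, adjusted p = 0.0644), Psma2 (0.87 ± 0.34), Psmd14 (0.90 ± 0.44) and Psmd7 (0.95 ± 0.47). On the deposited scale the median of the proteasome list was 6.02e-04, where the median of all probes was -0.57.

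NF-kappaB and innate signalling genes had a median rise of 0.77 over 16 genes, 14 of them positive (camera adjusted p = 7.61e-05, and adjusted p = 0.110 with an estimated correlation). Under 5 other scalings, which also moved the median of all probes, the median of this list ranged from 0.24 to 0.91. Only Saa3 passed the threshold, both over all probes and over the list alone. The next members were the adaptor Myd88 (1.02 ± 0.33, SE, adjusted p = 0.201), Nfkb2 (1.82 ± 0.61, adjusted p = 0.223) and the adhesion molecule Vcam1 (1.66 ± 0.63, adjusted p = 0.256, with 0.34 at its other tested probe). Chemokines and cytokines had a median of 1.19 over 9 genes, 6 of them positive (camera adjusted p = 0.0218, and adjusted p = 0.301 with an estimated correlation). Members of this list went both ways past the threshold, with Ccl5 higher and Cxcl12 lower, and 4 higher and 1 lower when adjusted over the list alone. Ccl7, a monocyte chemokine, had 2.71 ± 0.53 (adjusted p = 0.0579), Cxcl16 had 1.29 ± 0.33 and Csf1 had 1.49 ± 0.51. The list missed the threshold in 8 of 30 alternatives, among them those without infected sample 3 or 4.

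Extracellular matrix genes fell together, with a median log2 fold change of -0.82 over 33 genes of which 29 were negative (camera adjusted p = 8.59e-07, and adjusted p = 0.249 with an estimated correlation). Col6a1 and Postn (periostin, -2.04 ± 0.36, SE) passed the threshold, and 11 genes were lower and 1 higher when adjusted over the list alone. With the random block the limma adjusted p of Col6a1 and Postn were 0.452 and 0.9997. Mmp12, the macrophage metalloelastase, had -2.02 ± 0.40 (adjusted p = 0.0579), and Eln, elastin, had -2.68 ± 0.55 (adjusted p = 0.0612), and its other tested probe passed (-2.63, adjusted p = 0.0269). Col1a1 was at -1.46 ± 0.77 (adjusted p = 0.392), with 0.04 in infected samples 1 and 2 and -2.97 in infected samples 3 and 4. Fibroblast markers had a median of -1.08 over 12 genes, 10 of them negative (camera adjusted p = 0.00115, and adjusted p = 0.110 with an estimated correlation). Postn alone passed over all probes, and 3 were lower when adjusted over the list alone. Dcn (-1.68 ± 0.42), Pdgfra (-1.67 ± 0.51) and Tcf21 (-1.13 ± 0.52) had adjusted p of 0.119, 0.191 and 0.333.

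Macrophage and leukocyte markers were negative in all 9 measured genes, with a median of -0.86 (camera adjusted p = 1.63e-04, and adjusted p = 0.166 with an estimated correlation). C1qa and the lysozyme gene Lyz2 (-2.14 ± 0.35, SE, adjusted p = 0.0347) passed the threshold, and 4 genes did when adjusted over the list alone. With the random block the limma adjusted p of C1qa and Lyz2 were 0.360 and 0.633. The other chains of complement C1q had -1.68 ± 0.36 (C1qc, adjusted p = 0.0698) and -1.36 ± 0.32 (C1qb, adjusted p = 0.102). Epicardial and mesothelial markers did not pass (median -0.24 over 7 genes, adjusted p = 0.885). Too few genes were measured to test smooth muscle and pericyte markers (4 genes, median -1.27), endothelial markers (3 genes, -0.61), skeletal myoblast markers (2 genes, 0.06) and erythroid markers (1 gene, -0.63), and no neural marker was measured.

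Sarcomere genes fell, with a median of -0.74 over 21 genes of which 18 were negative (camera adjusted p = 3.89e-04, and adjusted p = 0.110 with an estimated correlation). Titin alone passed the threshold, both over all probes and over the list alone. Its call rests on 1 of 7 probes, the only one that could be tested. The ventricular and atrial light chain genes Myl2 (-1.33 ± 0.40, SE) and Myl4 (-1.24 ± 0.45) and the Z-disc gene Ldb3 (-1.0 ± 0.38) had adjusted p of 0.191, 0.242 and 0.256. The median of the list was -0.51 in infected samples 1 and 2 and -1.14 in infected samples 3 and 4. Calcium handling and ion channel genes had a median of -0.85 over 11 genes, 9 of them negative (camera adjusted p = 0.0406, and adjusted p = 0.547 with an estimated correlation), with 0 past the threshold over all probes and 2 when adjusted over the list alone. Jph2, junctophilin, had -1.26 ± 0.31, the calcium store protein gene Casq2 had -1.77 ± 0.50, Kcne1 had -1.63 ± 0.62 and Hrc had -1.08 ± 0.62. This list missed the threshold in 13 of 30 alternatives, among them those without control sample 3 or 4, without infected sample 3 or 4 and on the deposited scale.

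Oxidative phosphorylation genes had a median of -0.64 over 45 genes, 37 of them negative (camera adjusted p = 7.61e-05, and adjusted p = 0.166 with an estimated correlation). None passed the threshold singly, over all probes or over the list alone. The smallest p belonged to the succinate dehydrogenase genes Sdhb (-1.46 ± 0.34, SE, adjusted p = 0.0934) and Sdhd (-1.05 ± 0.31) and the complex I genes Ndufc1 (-1.10 ± 0.33) and Ndufa1 (-1.09 ± 0.34). The median was -0.27 in infected samples 1 and 2 and -0.88 in infected samples 3 and 4, and ranged from -1.17 to -0.48 under 5 other scalings. Fatty acid oxidation genes had a median of -0.76 over 19 genes, 15 of them negative (camera adjusted p = 0.00101, and adjusted p = 0.385 with an estimated correlation), with 0 past the threshold over all probes and 2 over the list alone. The fatty acid transporter gene Cd36 had -2.17 ± 0.44 (adjusted p = 0.0597), Etfdh had -1.51 ± 0.34, Eci2 had -1.08 ± 0.41 and Hadhb had -1.19 ± 0.46. The other tested probe of Cd36 gave -1.38 and that of Hadhb gave -0.60. The median of the list was -0.34 in infected samples 1 and 2 and -1.46 in infected samples 3 and 4. Glycolysis and glucose uptake genes did not pass (median -0.22 over 21 genes, adjusted p = 0.541).

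Cell cycle genes had a median of -0.78 over 25 genes, 20 of them negative (camera adjusted p = 3.50e-04, and adjusted p = 0.144 with an estimated correlation). None passed the threshold, over all probes or over the list alone. The ribonucleotide reductase gene Rrm2 had -1.12 ± 0.29 (SE, adjusted p = 0.134), the proliferation marker Mki67 had -1.65 ± 0.44, Tk1 had -1.30 ± 0.39 and Top2a had -1.50 ± 0.46. Cytosolic ribosomal protein genes had a median of -0.27 over 58 genes, 39 of them negative, and passed narrowly (camera adjusted p = 0.0398). They missed the threshold with an estimated correlation (adjusted p = 0.385) and with the presumed pairs as a random block (adjusted p = 0.0723), and in 17 of 30 alternatives in all. None passed singly. Rplp0 had -1.16 ± 0.32, Rpl22 had -1.54 ± 0.46, Rps15 had -1.52 ± 0.51 and Rpl31 had -0.93 ± 0.32. The other tested probe of Rpl31 gave 0.72 and that of Rps15 gave -0.12.

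**Figure D2:**
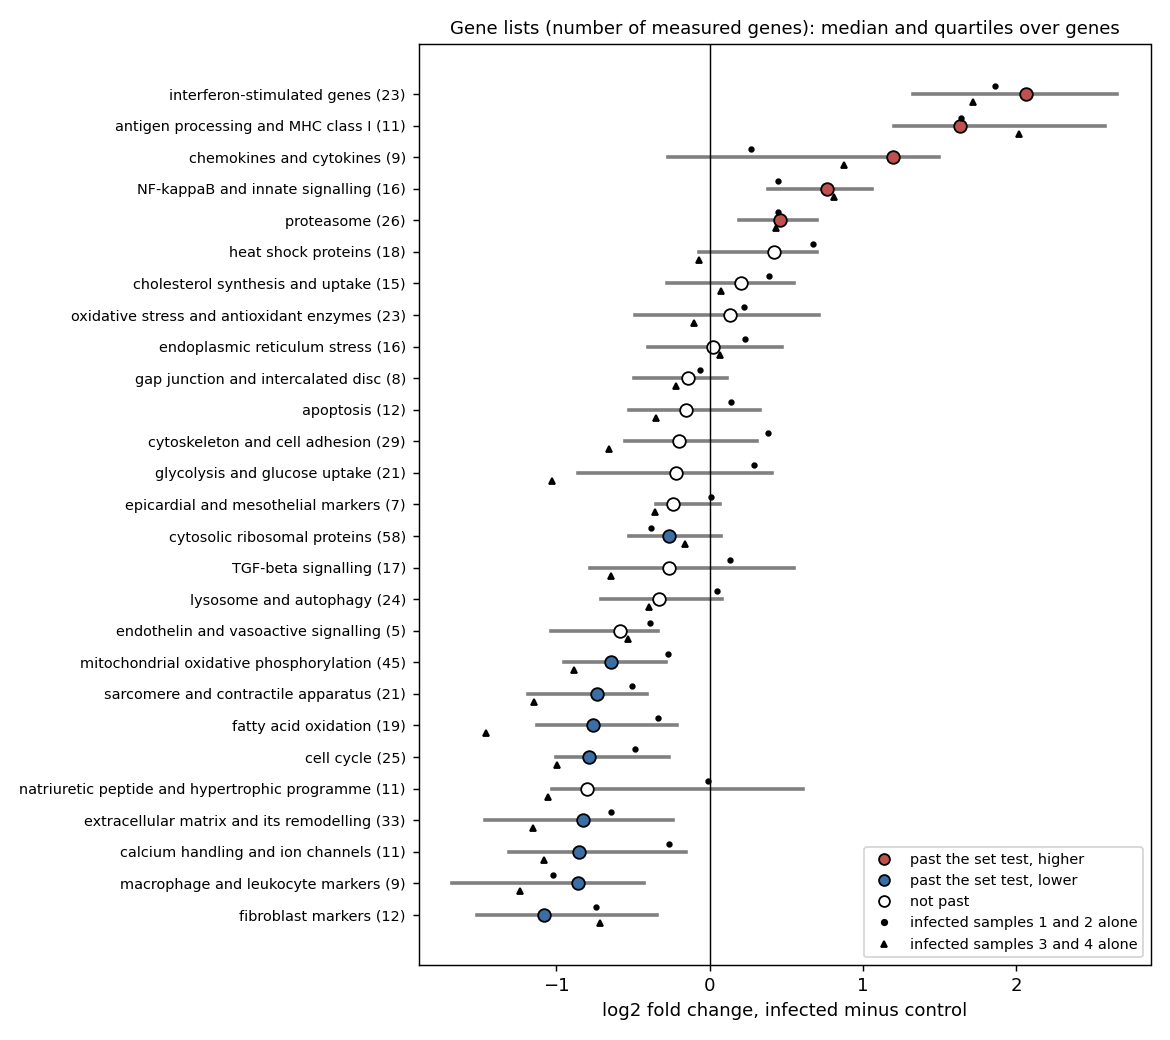
Median log2 fold change, infected minus control (x axis), of the measured genes of each of the 27 lists tested (y axis, number of genes in brackets), with the quartiles over genes as bars. Filled circles passed the camera test, and small symbols give the median for infected samples 1 and 2 and infected samples 3 and 4 against all controls. The interferon list has the highest median (2.06) and the fibroblast list the lowest (-1.08).

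The lists that did not pass the camera test had the following medians. Heat shock proteins had 0.42 (adjusted p = 0.0867), lysosome and autophagy -0.33 (0.0959), endothelin and vasoactive signalling -0.58 (0.155), natriuretic peptides and the hypertrophic programme -0.80 (0.214) and cholesterol synthesis and uptake 0.20 (0.360). TGF-beta signalling had -0.27 (0.541), oxidative stress 0.13 (0.541), gap junction and intercalated disc -0.14 (0.561), endoplasmic reticulum stress 0.02 (0.599), cytoskeleton and adhesion -0.20 (0.651) and apoptosis -0.15 (0.885). Within these lists only Tgfb2 passed the threshold (-2.02 ± 0.37, SE, adjusted p = 0.0467, and 0.704 with the random block).

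Several genes were to be reported whatever their result, and none of those tested passed the threshold. The gap junction gene Gja1 (connexin 43) had -0.92 ± 0.41 (SE, adjusted p = 0.320), Edn1 (endothelin) -1.03 ± 0.37 (adjusted p = 0.233) and the calcium pump gene Atp2a2 -1.36 ± 0.79 (adjusted p = 0.446). Il6 had 1.19 ± 0.58 (adjusted p = 0.356), Ptgs2 0.87 ± 0.61 (adjusted p = 0.534), Hmox1 0.45 ± 0.40 (adjusted p = 0.617), Tgfb1 0.42 ± 0.77 (adjusted p = 0.834) and Gapdh -0.22 ± 0.48 (adjusted p = 0.866). The infected samples of several of these parted by presumed array. Tgfb1 was 1.74 over the controls in infected samples 1 and 2 and -0.89 in infected samples 3 and 4, and Atp2a2 was at 0.08 and -2.80. The 19 other tested probes of Gapdh ranged from -0.91 to 2.07. Ccl2, Cxcl10, Nppa and Actb had too few values for a test, and no probe was annotated to Myh6. On the deposited scale centred on the shared spots, the monocyte chemokine gene Ccl2 averaged 2.29 in 4 controls and 6.00 in infected samples 3 and 4, and had no value in infected samples 1 and 2. Nppa averaged 5.81 in 2 controls and 6.53 in 2 infected samples.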

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

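A sample lay far from the other 3 of its group in 5 of 216 checks of named genes, list scores and spot counts, where chance gives about 1 in 20. Each ratio below is the gap to the nearest other sample over the range of the group. Infected sample 1 was lowest for H2-K1 (ratio 0.886), and infected sample 3 was highest for Ecrg4 (0.890). Infected sample 2 was lowest for C1qb (0.913). Control sample 4 had the lowest score of the ribosomal proteins (0.977), and infected sample 1 the highest score of the epicardial markers (0.854).

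Some members of the fixed lists had values in all 4 infected samples but in at most 2 controls, so they were not tested. In the genes given next every infected value lay above every control value. Their infected means, as log2 values centred on the shared spots, were 2.59 for Cxcl10, 1.20 for Oasl1, 1.11 for Cxcl1, -0.47 for Oas2, -0.57 for Mx2, -0.63 for Psmb9 and -1.90 for Tap2. They were -0.50 and -0.27 for the 2 probes of Lcn2, -2.37 for Tlr2 and 2.92 for Psmb7. The means of 2 controls were -2.33 for Cxcl10, -3.29 for Oasl1, -2.59 for Cxcl1, -3.08 for Oas2, -3.15 for Psmb9, -3.81 for Tap2 and 2.27 for Psmb7, so Psmb7 differed little. The value of 1 control was -2.87 for Mx2, -4.34 and -4.37 for Lcn2 and -4.10 for Tlr2. The control values of Lcn2 and Tlr2 lay below the lowest value of any spot in the infected samples, so their order could not differ. The lowest value of any spot differed between samples. The control means of Tap2, Oasl1 and Psmb9 lay below it in some infected samples, so their order was partly fixed too. Other list members with this pattern of values overlapped or went the other way. For Fabp3 every infected value lay below both controls (means 2.45 and 3.46), and Ccl9 (2.15 and 2.81) and Ctsh (1.32 and 1.99) had lower infected means.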

How the results depend on the processing

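The alternatives that used the deposited values, other treatments of the block medians, pair means, presumed arrays left out or a term for the sample structure were chosen after the result was seen. The number of probes past the threshold moved from 68 (40 higher, 28 lower) in many settings, and the cause was not tested. It was 113 (64 higher, 49 lower) without a dye term, 57 (40 and 17) with the dyes of the protocol, 3 (3 and 0) with the replicate number as a block and 2 (2 and 0) with the random block. The replicate numbers do not pair the samples. One sample left out gave 6 to 78 probes (5 to 53 higher, 1 to 25 lower). The deposited values gave 62 (13 and 49), blocks centred on shared spots 132 (68 and 64), recovered intensities 34 (23 and 11) and pair means 1 (1 and 0). Leaving out control samples 1 and 2 gave 2 (2 and 0), control samples 3 and 4 0 (0 and 0), infected samples 1 and 2 1079 (457 and 622) and infected samples 3 and 4 182 (116 and 66). The term for the crossed split gave 316 (147 and 169), and 50 (29 and 21) with the random block. An adjusted p under 0.1 gave 165 (83 and 82), and an unadjusted p with a 1.5-fold change 1230 (513 and 717). All probes called had the same sign in every setting that tested them. The number of lists past the threshold moved from 14 to 2 with an estimated correlation, a test run only on genes with values in all 8 samples.

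Some values that did not pass the threshold changed direction. Leaving out infected samples 3 and 4 gave 0.0817 for Atp2a2, 0.0443 for Col1a1, 0.54 for Gapdh, -0.015 for the natriuretic list, 0.30 for glycolysis, 0.14 for TGF-beta, 0.39 for cytoskeleton and 0.00689 for epicardial markers. Leaving out infected samples 1 and 2 gave -0.88 for Tgfb1, -0.0133 for Ptgs2 and -0.0995 for Hmox1. Leaving out control samples 1 and 2 gave -0.34 for Tgfb1, 0.0195 for Gapdh and -0.27 for apoptosis, and leaving out control samples 3 and 4 gave 0.16 for glycolysis, 0.24 for cytoskeleton and 0.16 for epicardial markers. The deposited values gave -0.14 for Tgfb1 and -0.0223 for Hmox1, and recovered intensities 0.0229 for Gapdh and 0.0182 for epicardial markers. The replicate block gave 0.18 for Gapdh, complete probes -0.0352, an estimated correlation -0.14 and the mean of probes -0.0867 for apoptosis, and loess -0.0193 for cytoskeleton. A list is a median here and its direction that of the camera test, so a median may keep its sign. With single samples left out the values ranged from -0.16 to 1.07 for Tgfb1, -0.65 to 0.19 for Gapdh, -0.65 to 0.0539 for glycolysis, -0.41 to -0.0908 for TGF-beta, -0.32 to 0.0788 for apoptosis, -0.52 to 0.0353 for cytoskeleton and -0.36 to 0.0253 for epicardial markers.

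Of the lists past the threshold, the interferon and antigen processing lists passed in all 30 alternatives. The other 12 were lost in 1 to 17, most often the ribosomal proteins (17), calcium handling (13) and chemokines (8). Of the lists not past it, heat shock proteins passed in 6, the natriuretic list in 2, and the endothelin and lysosome lists in 1 each. Camera compares a list with other genes, so passing with the random block or on pair means does not test the dependence within pairs.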

Other observations

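The tests in this part were chosen after the results were seen, except the counts over other splits and the comparison of fibroblast with epicardial markers. Further genes past the threshold, named after their values were seen, included Parp14 (2.64), Parp12 (2.04), Trex1 (2.19), Ifi204 (2.67), Ube2l6 (2.02), Batf (1.97) and Lgals3bp (1.81), all higher in infected cultures on the log2 scale. Parp14, Parp12, Ifi204 and Ube2l6 are known to be induced by interferon. The basement membrane gene Nid2 (-1.58) was lower. Other genes passed at a probe that does not represent them. Lyz1, a near copy of Lyz2, had -3.65 at such a probe and -2.08 at its brighter one, Ccdc80 had -2.31 and -2.10, and Eln had -2.63 and -2.68. Trim30a had 2.65 and 1.45. Tnfrsf12a had -1.76 but 0.87 at its brighter probe, and Smarca4 had 1.91 but -0.40. A further 14 of the 68 probes had no single gene symbol.

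Untested spots with 1 symbol had values in all 4 infected samples and at most 2 controls in 152 cases, and in all 4 controls and at most 2 infected samples in 945 cases. Of the first, 6 belonged to the interferon or antigen processing lists, and of the second 2 did. Fisher's exact test of these counts gave p = 1.43e-04, but it was chosen after the pattern was seen in the same genes and counts spots as independent, so it adds no evidence. Serpinb2 and Sdf2 were the named genes with values in all 4 infected samples and no control. Il18bp, which encodes the interleukin-18 binding protein, Ly6e and H2-Q8 had values in all 4 infected samples and 1 control. These genes were named after their values were seen.

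Of the 35 splits of the 8 samples into 4 and 4, 2 gave at least as many probes as the real one (68, and 493 for the highest other), and 2 gave at least as many lists (14, and 15 for the highest other). Chance can therefore not be excluded by these counts. The split with 493 probes joined control samples 1 and 2 with infected samples 3 and 4, which points to a structure of the samples that called more probes than the infection. The split with 15 lists exchanged 1 sample of each group and so still held a part of the contrast. Only 3 splits keep the presumed arrays whole, too few for a share under 0.05, and the other 2 gave 0 and 493 probes and 0 and 2 lists. The median recovered intensity of shared spots was 560, 285, 348 and 351 in control samples 1 and 2 and infected samples 3 and 4 and 1532, 691, 678 and 731 in the other 4. All 68 probes had the same sign when infected samples 3 and 4 were set against control samples 1 and 2 and when infected samples 1 and 2 were set against control samples 3 and 4, but these are the same values from which they were called. Over all probes, which are not independent, these 2 comparisons correlated at 0.077.

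The rise of the interferon and class I lists did not rest on 1 presumed infected array, since the lowest median of either list in either array was 1.64. It was not removed by the scaling, since the lowest median of either list under 5 other scalings was 1.13. More leukocytes in the infected cultures would raise leukocyte markers, whose median was -0.86. Of the 20 markers listed 9 were measured, and the list did not pass camera with an estimated correlation (adjusted p = 0.166). The T cell marker Cd3e had too few values for a test. The rise is a candidate response of the cultured cells to the infection. For infected samples 3 and 4 against control samples 1 and 2, the medians were 1.95 (interferon) and 1.65 (class I). For infected samples 1 and 2 against control samples 3 and 4 they were 1.72 and 2.09. The medians of the infected arrays differed by 0.14 and -0.38, which argues against an effect that varies from array to array. Infected and control samples lay on separate presumed arrays, so an effect shared by both infected arrays stays open and untested, as do effects of the inoculum other than infection.

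The sarcomere and oxidative phosphorylation lists fell with the preset correlation, but did not pass with an estimated correlation (adjusted p = 0.110 and 0.166). A lower share of non-muscle cells alone would raise sarcomere genes, whose median was -0.74. A shift that depends on spot brightness is argued against too, since the higher of the 2 lists' percentiles among 10000 random lists of the same brightness was 0.03. In the sarcomere list the fall was -1.09 for infected samples 3 and 4 against control samples 1 and 2 and -0.17 for infected samples 1 and 2 against control samples 3 and 4, so its size may depend on the array. In the oxidative phosphorylation list these were -0.66 and -0.70. Loss or damage of myocytes and RNA of the parasite in the sample stay open and were not tested.

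The matrix and fibroblast lists fell with the preset correlation, but did not pass with an estimated correlation (adjusted p = 0.249 and 0.110). A lower share of all non-muscle cells alike would move fibroblast and epicardial markers together, but their scores moved apart by -0.95 between the groups (exact permutation p = 0.0286, the smallest possible, with the 8 samples counted as independent). The epicardial score rests on 5 genes. Smooth muscle and pericyte markers (median -1.27 over 4 genes, all negative) and endothelial markers (-0.61 over 3 genes, 2 negative) were lower too, but too few for a test. A lower share of most non-muscle cells therefore stays open. Spot brightness is argued against, since the higher of the 2 lists' percentiles among random lists was 0. A lower share of fibroblasts and macrophages alone, whose markers were both lower with the preset correlation and with fry but not with an estimated correlation, may account for part of the pattern and stays open, as does lower expression per cell. Of the 12 fibroblast markers measured, Col1a1, Col1a2, Col3a1, Dcn, Fbln1 and Postn are also in the matrix list, so the lists are not independent.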
